A study of Drosophila melanogaster with 10 samples.

How the data were processed

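RNA was measured on 10 spotted two-colour arrays of Drosophila melanogaster. Per the labels, 7 arrays carried total RNA of females labelled CS and orbdec, 5 with CS in Cy3 and 2 with CS in Cy5, from 1 RNA sample per genotype. The other 3 arrays carried RNA from immunoprecipitates of ovary extracts, from females 2 to 3 days old. On 1 of them an Orb IP (antibody 6H4) was set against an anti-HA control IP (antibody 12CA5), and on 2 of them Orb IPs were set against ovarian poly(A) RNA with the dyes exchanged. Of 3 Orb IP samples described, each array took 1; the control IP and the poly(A) RNA were 1 sample each. The series text describes all samples as coming from w1118 females, which is at odds with the CS and orbdec labels, and the groups follow the sample labels. For the array against the control IP the title gives Cy3 for both RNAs and the channel field gives Cy5 for the control IP, and the channel field was followed.

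Per the labels' protocols, the authors removed poor spots by hand, such as those on bright background, and subtracted a local background from each spot. The deposited values are normalized log ratios of the dyes, read here as log10. The normalization method, the scanner software, the log base and the dye in the numerator are not given in the sources used here. Array means of the deposited values lay within 0.0031 of 0, and medians ran from -0.016 to 0.038. Spot intensities were not used here, so no signal level could be matched or filtered on. In the array against the control IP, 5 failed values were set to missing. All columns of per-sample values were used.

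The log base was inferred from control positions printed in each of 24 blocks. Offsets were measured from the median of 5 other control kinds on the same array, taken as equal in both dyes. In deposited sign that median was 0.92 and -1.05 on the arrays against poly(A) RNA with the IP in Cy3 and in Cy5. On the others it ran from -0.26 to -0.06. On 5 of the 10 arrays, pairs of control kinds were offset by 0.49 ± 0.09 and 1.07 ± 0.05 (SD) in size. This is close to the log10 of 3 and 10, 0.477 and 1. On the 5 arrays with CS in Cy3 the same controls were offset by only 0.09 ± 0.04. Reading the values as log2 is given as an alternative. The rules fixed in advance assumed log2 ratios, and their 2-fold threshold was applied as 0.301 in log10.

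Positions were named through the platform annotation, but the deposited row number did not match the order of that annotation. This naming was settled only after the data were seen. Of 64 reading orders of a grid with 24 blocks of 16 rows and 41 columns, or 656 spots per block, the order was taken in which 2 probes of the same gene had the most similar genotype ratios. Their correlation over 546 gene pairs was 0.512 in the chosen order, 0.0201 by deposited row number, at most 0.120 in the 63 other orders and at most 0.129 over 1000 random pairings. For the IP ratio it was 0.295, 0.112 by row number and at most 0.257 in the other orders. Of the 10 most extreme block positions, 7 held no gene in any block in the chosen order and 1 by row number, but some of the other orders reached 7 too. As a check not used in the choice, 19 of 24 fixed gene lists had a median outside the middle 95% of random lists under the chosen order and 2 of 24 by row number. All gene names depend on this order.

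Of 15744 positions, 13146 had 1 gene, 99 several and 2499 none, and 960 positions with control or blank spots (40 per block, where at least 90% of blocks had no gene) were left out. Symbols of 12518 positions were updated through their Entrez identifier in a gene table of assembly Release 6, which was used only for names and neighbours, and 628 kept the annotation's name. Probes of 1 gene symbol were averaged within an array. This gave 13873 features, 12235 of them named genes, of which 688 had several probes; 340 of these had at least 1 probe called, 77 had all probes called on 1 side and 27 had probes called on opposite sides.

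Signs were turned so that orbdec or Orb IP RNA counted as if in Cy5. For the genotype ratio the mean of the 5 arrays and the mean of the 2 swapped arrays were averaged with equal weight, so that dye effects of equal size in both cancel. A feature needed 3 of the 5 and 1 of the 2 arrays. It was called when the mean was at least 2-fold and every array that measured it had the same sign. This is a rule of size with no test, since the arrays repeated 1 RNA sample per genotype. The IP ratios against poly(A) RNA were tested against 0 with limma (lmFit and eBayes) and Benjamini-Hochberg adjustment at 0.05, which leaves out the spread of the single poly(A) sample, and were also counted at 2-fold or more on both arrays. The IP samples are called separate in the series text, and the spread may still be technical in part. The control IP array was counted at 2-fold. Overlaps were set against the number expected of independent lists and tested with Fisher's exact test across features, one-sided for the 3 IP arrays and two-sided for the genotype.

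The design, the alternatives, the 28 gene lists and the naming rule were set before the data were examined. The rule named orb first, then per comparison the 10 called genes with the largest change on each side, then up to 4 called members of each list, or 2 with the largest values where none was called. A gene named through 1 comparison may be given with its value in another, and not all of these genes are described. List medians were placed among 10000 random lists of the same size where 5 or more members were measured. These percentiles describe the RNA samples and are not tests. Synonyms of at most 3 letters were no longer matched, except where only the case differed, after the data were seen, which took svp off the testis list. The P450 pattern also takes in Cyp1, a cyclophilin gene, the accessory gland list holds Acp1, a cuticle gene, and the vitelline membrane list holds fs(1)Ya, a nuclear envelope gene. The log10 reading, on which all folds and counts rest, was adopted after the data were seen, in place of the log2 ratios first assumed. Centring on print rows, the log2 reading as an alternative, naming by row number, matching random lists on print row and 12 further gene families were also added then.

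Also set before the data were examined were these other ways to obtain the results: other centring and scaling, other weights of the dye orientations, thresholds of 1.5-fold and 3-fold, no sign requirement, other filters, limma over the 7 arrays with a dye term, with the slide series (2 series of slides) as a term or with the replicate number as a block, probes kept apart, and leaving out each array.

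The calling rules were tested on simulated data with 50 features at each of 4 folds. The genotype rule called 0% of features at 1.5-fold, 96% at 2.5-fold and 100% at 8-fold among 13281, and 2 of 13081 unchanged features. For the IP ratio, limma's result depended on the noise assumed, among 13121 features. With each feature's own SD over 2 arrays as its noise, which was the first version of the test, limma called 0% at every fold, and the 2-fold rule called 70% at 2.5-fold and 92% at 4-fold, with 159 of 12921 unchanged features called. The noise was then also drawn from the variance distribution that limma fitted to these arrays (prior degrees of freedom 14.0), which favours limma. It then called 30% at 2.5-fold, 88% at 4-fold and 100% at 8-fold, with 5 unchanged features called, and the 2-fold rule called 58%, 96% and 100%, with 52 unchanged features called. The counts by limma for the IP therefore rest on features sharing 1 variance distribution. In both versions the noise was drawn feature by feature, without differences between print rows. Such differences held 42.9% of the variance of the real IP ratio against poly(A) RNA. The numbers of unchanged features called therefore do not give the rate of false calls on these arrays.

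Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and statmod 1.5.0.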

Results

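RNA from Drosophila females and ovaries was compared on 10 two-colour spotted arrays, in a study of RNAs regulated by Orb. Orb is a cytoplasmic polyadenylation element binding protein of the female germline that controls translation of localized oocyte messages. The series falls into a genotype part and an immunoprecipitation part. In the genotype part, total RNA of females labelled CS and of females labelled orbdec, named after a mutant allele of orb, was hybridised on 7 arrays. CS was in Cy3 on 5 of them and in Cy5 on the 2 dye-swapped ones. Only 1 RNA sample was described per genotype, so the 7 arrays were technical repeats, and no test between the genotypes was possible. Their SD holds hybridization error and the difference between the dye orientations. It counts each array equally, while the mean given with it weights the 2 orientations equally, so it is not the error of that mean. In the immunoprecipitation (IP) part, ovary extracts were treated with the anti-Orb monoclonal antibody 6H4, giving 3 samples, or with the anti-HA antibody 12CA5 as control, giving 1 sample. RNA from the Orb IPs was set against the control IP on 1 array and against 1 sample of ovarian poly(A) RNA on 2 arrays with the dyes exchanged. The arrays gave log ratios for 14849 to 15739 of 15744 positions, and the number of arrays limited their precision.

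The labels gave the dye of each RNA but not which dye was the numerator of the deposited ratio. Values are therefore given by side. The positive side is the sign carried where orbdec RNA or Orb IP RNA was in Cy5, after arrays of the opposite orientation had been turned. It means more RNA in orbdec or in the IP if the ratios were Cy5 over Cy3, and less if they were Cy3 over Cy5. Every side would change together, so relations between comparisons hold under either reading as long as all arrays used the same order. The labels of the control IP array conflict on its dyes, so the side of that array could also turn alone. Values are read as log10 ratios, from the ratio control spots, and folds are the sizes that this reading gives. Gene names rest on a re-indexed order of the array positions that was chosen after the data were seen.

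Between orbdec and CS females, orb itself lay on the positive side on each of the 7 arrays. Its turned log10 ratio was 1.05 to 1.24 on the 5 arrays with CS in Cy3 and 0.70 to 0.80 on the 2 swapped arrays. The dye-balanced mean was 0.94 ± 0.19 (SD, n = 7 arrays), a difference of 8.71-fold. With the direction open, this value does not check the genotype labels. The size of the difference exceeded 2-fold, with 1 sign on every array, for 1586 features on the positive side and 1470 on the negative side among 13845 measured, or 11.5% and 10.6%. Of 12214 measured genes with names, 1404 were on the positive and 1343 on the negative side.

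Eggshell and oocyte genes led the positive side. The largest mean log10 ratio was that of Cp19, a chorion protein gene, at 1.80 ± 0.35 (SD, n = 7 arrays), a 63.3-fold difference. It was followed by the chorion gene Cp16 at 1.71 ± 0.33, the vitelline membrane gene Vm26Aa at 1.65 ± 0.43, the female germline thioredoxin gene dhd at 1.64 ± 0.20 and the vitelline membrane gene Vm34Ca at 1.60 ± 0.51. CG7101 at 1.57 ± 0.09, the chorion genes Cp36 at 1.54 ± 0.43, Cp15 at 1.49 ± 0.49 and Cp38 at 1.48 ± 0.46, and the germ plasm organizer osk at 1.48 ± 0.30 completed the first 10. Of 10 measured chorion genes, 9 were called on the positive side and 0 on the negative, with a list median of 1.46. All 7 measured genes of the vitelline membrane list were called on the positive side, 1 of which, fs(1)Ya, encodes a nuclear envelope protein of the early embryo and not an eggshell protein. Among the others were psd at 1.24 ± 0.32 and Vm32E at 1.16 ± 0.21, and the median of all 7 was 1.16. Sizes depended on dye orientation: on the 5 arrays with CS in Cy3 and on the 2 swapped arrays the chorion median was 1.06 and 1.72, the vitelline membrane median 0.92 and 1.53, and Cp19 1.45 and 2.15. The 4 yolk genes split: yl, the oocyte yolk receptor, was at 1.15 ± 0.13, while the yolk protein genes Yp1 and Yp3 were on the negative side at -0.41 ± 0.10 and -0.33 ± 0.12. Yp3 was within 2-fold on the 2 swapped arrays alone.

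Maternal and translational regulators lay on the same side as the eggshell genes. Of 52 oocyte patterning and germ plasm genes, 31 were called on the positive side and 0 on the negative, with a median of 0.41. Besides osk they included exu, needed for bicoid RNA localization, at 1.25 ± 0.27, the cell cycle regulator of the early embryo gnu at 1.07 ± 0.15, and the germline RNA helicase gene vas at 1.06 ± 0.05. Among 28 genes of ribonucleoprotein (RNP) complexes and translational repression, 14 were positive and 1 negative, with a median of 0.35. Examples were the helicase gene me31B at 1.29 ± 0.17, BicC at 1.04 ± 0.10 and the cytoplasmic poly(A) polymerase gene wisp at 0.85 ± 0.09. Of the 4 mRNAs reported to be bound by Orb, orb and osk were called, whereas grk at -0.08 ± 0.03 and fs(1)K10 at 0.20 ± 0.20 were not. Of 11 follicle cell regulators only 3 were called, Cad74A at 0.45 ± 0.04, tj at 0.39 ± 0.25 and usp at 0.33 ± 0.14, and the list median of 0.03 lay at percentile 73.2 of 10000 random lists. On the 5 arrays with CS in Cy3 alone tj was within 2-fold, and on the 2 swapped arrays alone usp was.

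Genes of cell division and protein turnover were also on the positive side. Of 34 cell cycle and DNA replication genes, 28 were called there and 0 on the other, with a median of 0.61. They included the replication clamp PCNA at 1.18 ± 0.16, the cyclin genes CycB3 at 1.14 ± 0.12 and CycB at 1.06 ± 0.18, the mean of probes that differed widely, and the checkpoint kinase gene lok at 1.07 ± 0.09. Of 27 proteasome genes, 12 were positive and 0 negative, with Rpn5 at 0.49 ± 0.03 and Prosbeta6 at 0.44 ± 0.05. Translation factors gave 16 positive calls and 0 negative among 46, with the cap-binding repressor eIF4EHP at 0.66 ± 0.20 and the release factor eRF3 at 0.56 ± 0.10. Of 38 cytoplasmic ribosomal protein genes, 7 were positive and 0 negative, led by RpS5b at 1.31 ± 0.16, with RpL27 next at 0.43 ± 0.16. Of 70 mitochondrial ribosomal protein genes, 8 were positive and 0 negative, with mRpL21 at 0.48 ± 0.37 and mRpL12 at 0.46 ± 0.14. This positive share was near the 11.5% of all features, while the list median of 0.13 lay at percentile 99.99 of random lists. Both RpL27, on the swapped arrays, and mRpL21, on the other arrays, were within 2-fold in 1 of the 2 dye orientations.

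The negative side held genes of the body outside the ovary. The largest values were those of the chitinase gene Cht9 at -1.38 ± 0.06 (SD, n = 7 arrays), a 23.8-fold difference, and of the antifungal peptide gene Mtk at -1.34 ± 0.17. Next came lncRNA:CR32368 at -1.31 ± 0.18, CG8539 at -1.29 ± 0.07, the odorant-binding protein gene Obp99b at -1.29 ± 0.14 and the fat body gene Fbp2 at -1.28 ± 0.12. The flight muscle actin gene Act88F at -1.27 ± 0.12, the copper transporter gene Ctr1B at -1.24 ± 0.06 and the cuticle protein genes Acp1 at -1.22 ± 0.27 and Acp65Aa at -1.20 ± 0.30 were the rest of the first 10. Of 19 muscle genes, 17 were called on the negative side and 0 on the positive, with a median of -0.62. Besides Act88F, the calcium sensors TpnC4 and TpnC41C were at -1.01 ± 0.07 and -0.84 ± 0.05. Of 25 antimicrobial and immune genes, 18 were negative and 0 positive, with a median of -0.68 and with PGRP-SB1 at -0.99 ± 0.19 and DptB at -0.98 ± 0.08. Digestive enzymes gave 27 negative calls and 0 positive among 42, among them the protease gene Jon99Fi at -1.04 ± 0.20 and the maltase gene Mal-A8 at -1.03 ± 0.08.

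Fat body, sensory and detoxification lists lay on the negative side as well. Of 26 fat body and lipid genes, 15 were negative and 1 positive, including the lipocalin gene NLaz at -1.02 ± 0.11 and the storage protein gene Lsp2 at -0.77 ± 0.08. Of 14 phototransduction genes, 8 were negative and 0 positive, with the arrestin genes Arr1 at -0.67 ± 0.20 and Arr2 at -0.65 ± 0.09. Of 19 nervous system genes 7 were negative and 0 positive, and of 49 odorant-binding protein genes 16 were negative and 1 positive. Cytochrome P450 genes gave 28 negative and 3 positive calls among 82. Cyp28d1 was at -0.94 ± 0.07, Cyp6a2 at -0.89 ± 0.18, and Cyp6a19 stood on the other side at 1.45 ± 0.18. Glutathione S-transferases gave 10 negative calls and 1 positive among 35, led by GstE1 at -1.19 ± 0.12. Oxidative phosphorylation genes gave 11 negative calls and 0 positive among 72, with ND-B8, a complex I subunit, at -0.59 ± 0.10 and a list median of -0.15.

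Lists for male tissues did not stand apart from random lists. None of 28 testis genes was called, with a median of -0.04 at percentile 28.6, where topi was at 0.14 ± 0.11 and sa at -0.10 ± 0.23. The testis median was 0.09 on the 5 arrays with CS in Cy3 and -0.18 on the 2 swapped arrays, and the accessory gland median 0.11 and -0.12. Of 16 genes listed for the male accessory gland only Acp1 was called, and it encodes an adult cuticle protein, not a gland product. Of 7 visible marker genes, sn at 0.43 ± 0.07 was positive, ry at -0.63 ± 0.21 and st at -0.39 ± 0.10 were negative, and the median of -0.03 lay at percentile 47.2. The 9 heat shock genes split, with the small heat shock protein genes Hsp27 at 1.04 ± 0.07 and Hsp26 at 0.91 ± 0.05 positive and Hsp68 at -0.53 ± 0.24 negative. Of 4 Turandot stress genes, only TotC was called, at -1.16 ± 0.30.

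**Figure D1:**
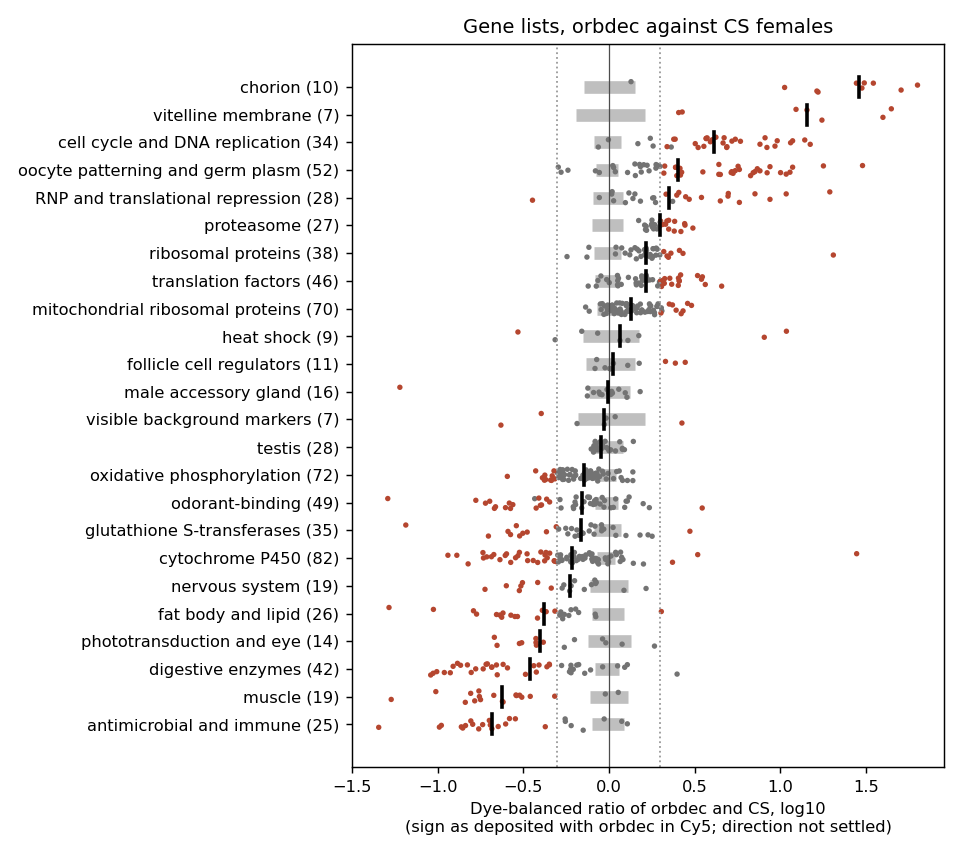
Each point is the dye-balanced log10 ratio of orbdec and CS RNA for 1 gene, grouped by gene list with the number of measured genes in brackets; called genes are red, black bars are list medians, grey bars span the middle 95% of medians of 10000 random lists, and dotted lines mark 2-fold. Chorion and vitelline membrane medians lay at 1.46 and 1.16, and the immune and muscle medians at -0.68 and -0.62.

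The arrays of each orientation repeated closely, and the orientations less so. Deposited ratios correlated across positions at r = 0.906 to 0.960 among the 5 arrays with CS in Cy3, at 0.880 between the 2 swapped arrays, and at -0.633 to -0.50 between the orientations, where the sign turns with the dyes. The median SD of a feature was 0.04 over the 5 arrays and 0.12 over all 7 turned arrays. Of 13281 features measured on all 7 arrays, 6235 (46.9%) kept 1 sign on all of them after turning. In 2898 (21.8%) each orientation had 1 sign and these were opposed, and the cause was not tested. Probes of 1 gene could differ: those of CycB were at 1.6 and 0.54, those of eIF4E1 at 0.72 and 0.36, orb2 had 4 probes from -0.50 to 0.34, and 27 of 688 genes with several probes had probes called on opposite sides.

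**Figure D2:**
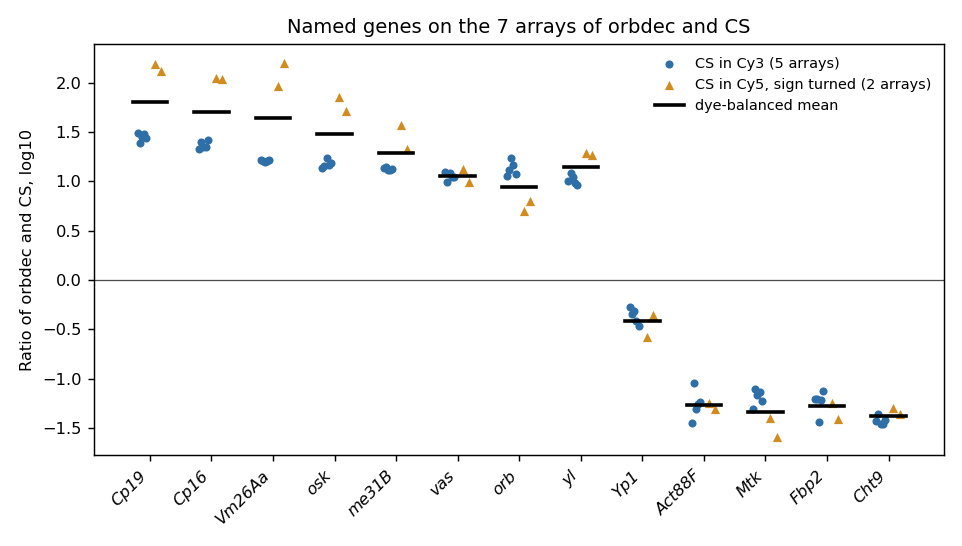
Turned log10 ratios of orbdec and CS RNA for 13 named genes on the 7 arrays, with blue circles for the 5 arrays with CS in Cy3, orange triangles for the 2 dye-swapped arrays and black bars for the dye-balanced mean. Values of orb ran from 0.70 to 1.24, and chorion genes such as Cp19 differed more on the swapped arrays than on the others.

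Orb IP RNA was compared with ovarian poly(A) RNA to look for messages associated with Orb in the ovary. This ratio holds no control IP, so it cannot separate binding by Orb from what any IP brings down. Against the control IP, only 1.36% and 1.08% of 13870 features were 2-fold or more on the positive and negative side. Of the genes named in this paragraph only galla-1, at 0.43, and CG10300, at 0.42 and so on its opposite side, were past 2-fold there. The 10 largest positive mean log10 ratios included Rnp4F, a spliceosome recycling factor, at 1.16 ± 0.03 (SD, n = 2 arrays), a 14.5-fold difference, and Mgtor, a nuclear pore basket protein gene, at 1.16 ± 0.34. Others were CG1142 at 1.10 ± 0.07, the ubiquitin ligase gene Roc2 at 1.10 ± 0.12, fmt at 1.08 ± 0.11, cyst at 1.08 ± 0.17, the replication checkpoint gene Claspin at 1.07 ± 0.09, the centrosomal protein gene Alms1a at 1.07 ± 0.11, Ciz1 at 1.07 ± 0.25 and galla-1 at 1.05 ± 0.07. On the negative side stood CG10300 at -1.20 ± 0.27, CG31253 at -1.20 ± 0.32, CG18063 at -1.08 ± 0.01, CG14325 at -1.03 ± 0.09, CG18131, CG18130 and CG18132 at -1.02 ± 0.05, -1.01 ± 0.08 and -0.95 ± 0.0042, the ciliary gene Gas8 at -0.98 ± 0.0071, beat-VII at -0.97 ± 0.0014 and the receptor kinase gene Ret at -0.96 ± 0.10. The message of orb was at -0.18 ± 0.27 and was not called (limma adjusted p = 0.20). Its 2 arrays gave -0.38 and 0.01.

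With limma, 3552 of 13121 measured features were on the positive side and 4173 on the negative. The threshold was a Benjamini-Hochberg adjusted p below 0.05, and the smallest was 7.5e-05. Control kinds taken as equal in both dyes lay far from 0, at deposited values of 0.92 with the IP in Cy3 and -1.05 with it in Cy5. Both are on the negative side once turned. Sides are thus relative to the 0 of the normalized ratio, and whether that 0 means equal amounts was not tested. At 2-fold or more on both arrays, 2264 (17.3%) were positive and 2754 (21.0%) negative. A large part of the variance, 42.9%, lay between the 16 print rows within the blocks of the array, against 3.16% for the genotype ratio. With each array centred on its print row, a step added after the data were seen, limma called 930 positive and 676 negative features, and 1199 and 986 passed 2-fold on both arrays. Of these, 850 and 349 were among the calls without centring. The share of positive calls among the 2-fold calls was 45.1% as deposited and 55.5% with arrays centred on their medians. All 20 genes named above kept their side and their 2-fold call after row centring. Their size alone made this likely, as row medians ran only from -0.45 to 0.36. After row centring orb reached -0.54 and was called negative.

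Lists of translational regulators had positive medians in the IP ratio, but fewer positive calls after row centring, where 1199 of 13121 features were positive. Of 52 oocyte patterning and germ plasm genes, 15 were positive and 2 negative at 2-fold on both arrays, and 9 and 3 after row centring. The RNA-binding protein gene stau was at 1.00 ± 0.11, the piRNA pathway gene rhi at 0.85 ± 0.31, the eggshell protease gene ndl at 0.78 ± 0.10 and the anterior determinant bcd at 0.71 ± 0.34, and these 4 kept their calls after centring. The dorsoventral signal gene grk was at -0.43 ± 0.0085 and lost its call after centring, at -0.06. By limma, 26 genes of this list were positive and 3 negative over all features tested, and 26 and 3 when adjusted over the list alone. Among 28 RNP and translational repression genes, 12 were positive and 1 negative, and 4 and 3 after centring, with 18 and 1 by limma over all features and 19 and 1 adjusted over the list alone. Translation factors gave 16 positive calls and 1 negative among 46, and 4 and 1 after centring, no larger a share than that of all features, with eIF4EHP at 1.00 ± 0.26 and eIF5B at 0.82 ± 0.07. Limma gave 25 and 5 of them over all features and 26 and 5 adjusted over the list alone. With random lists matched on print row, the medians of the oocyte and RNP lists lay at percentiles 98.96 and 98.2, and that of translation factors at 95.01, against 99.97 with free lists. Chorion genes, 10 measured, had 0 calls on either side, and 0 by limma under both adjustments.

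Housekeeping and cell cycle lists had more positive than negative calls in the IP ratio, although the shares of positive genes in the cell cycle and mitochondrial ribosomal lists were below the 17.3% of all features. With random lists matched on print row, the medians of the cell cycle (percentile 98.0 to 89.0), ribosomal (99.6 to 94.1) and heat shock lists (97.8 to 85.1) moved into the middle 95%, and that of the proteasome list moved out of it (96.6 to 98.4). Of 37 ribosomal protein genes, 10 were positive and 1 negative, with RpL15 at 0.61 ± 0.07 and RpS5b at 0.59 ± 0.0035, and 6 and 1 after centring. Oxidative phosphorylation genes gave 18 positive and 6 negative among 71, and 11 and 2 after centring, where the list median of 0.09 became -0.01. Mitochondrial ribosomal protein genes gave 9 and 5 among 70, and 5 and 1 after centring. Of 27 proteasome genes, 5 were positive and 0 negative, and 9 and 0 after centring. Among 34 cell cycle genes 5 were positive and 1 negative, including the checkpoint kinase gene grp at 0.77 ± 0.04 and E2f1 at 0.62 ± 0.13, and 4 and 0 after centring. Heat shock genes gave 3 positive and 0 negative among 9, before and after centring, led by Hsp27 at 0.86 ± 0.05.

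Lists of other tissues differed in the IP ratio, and several had more negative than positive calls. Of all features 21.0% were negative as deposited, and 986 of 13121 after row centring. As deposited, the negative shares of the P450, digestive, immune, fat body, nervous system, phototransduction and muscle lists lay below that of all features. Of 43 odorant-binding protein genes, 0 were positive and 21 negative, but 0 and 2 after row centring. Testis genes gave 1 positive and 10 negative calls among 28, and 0 and 3 after centring, with the sperm tail protein genes Mst84Dc at -0.61 ± 0.02 and Mst84Dd at -0.59 ± 0.08, which lost their calls after centring, at -0.24 and -0.22. Of 78 cytochrome P450 genes, 9 were positive and 15 negative, and 3 and 17 after centring. Male accessory gland genes gave 0 and 4 among 14, and 0 and 6 after centring, with Acp95EF at -0.79 ± 0.10. Digestive enzymes gave 3 and 6 among 41, and 2 and 8 after centring, and the 18 immune genes 2 and 2, and 1 and 6 after centring. Fat body and lipid genes gave 5 positive and 3 negative among 25, and 2 and 2 after centring, and nervous system genes 3 and 2 among 18, and 0 and 2 after centring. Of 14 phototransduction genes 1 was positive and 0 negative, and 1 and 3 after centring, and of 19 muscle genes 0 were positive and 2 negative, and 0 and 1 after centring. Glutathione S-transferases gave 6 and 8 among 35, and 2 and 1 after centring.

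**Figure D3:**
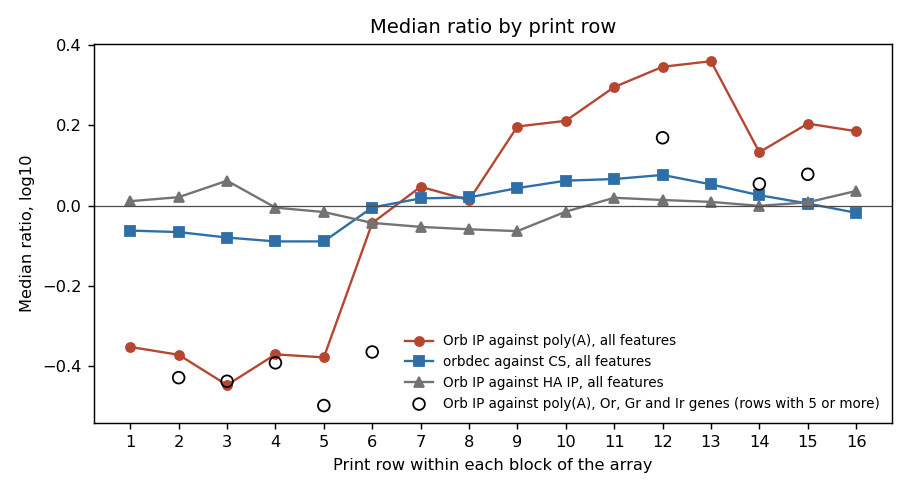
Median log10 ratio of features in each of the 16 print rows for Orb IP against poly(A) RNA, orbdec against CS and Orb IP against HA IP, with open circles for odorant, gustatory and ionotropic receptor genes (Or, Gr and Ir) in rows that hold 5 or more of them. The IP against poly(A) medians ran from -0.45 to 0.36, and those of the genotype ratio from -0.09 to 0.08.

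The array of Orb IP RNA against control IP RNA compared the antibodies directly, on 1 array without a dye swap or replicate. Largest on the positive side were the odorant receptor gene Or98a at 1.10, the dynein adaptor gene BicD, which acts in RNA transport to the oocyte, at 0.88, the actin regulator Vrp1 at 0.83 and the peptidoglycan recognition gene PGRP-SC1b at 0.67. The myosin kinase gene sqa at -0.98, CG7694 at -0.90, gnu at -0.74, the ammonium transporter gene Rh50 at -0.72, the ribosomal stalk gene RpLP2 at -0.70, dhd at -0.69 and Hsp26 at -0.58 were on the negative side. The message of orb was at -0.13 and osk at -0.20, both within 2-fold. Of 13870 features, 189 (1.36%) were 2-fold or more on the positive side and 150 (1.08%) on the negative.

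Ribosomal protein and chorion genes lay on the negative side of this array. Of 38 ribosomal protein genes, 0 were positive and 13 negative, with a median of -0.17 below all 10000 random list medians, and with RpL37A at -0.49 and RpS28b at -0.48. Of 10 chorion genes, 0 were positive and 4 negative, with a median of -0.16 and with Cp15 at -0.47 and Cp36 at -0.45. Of the 52 oocyte patterning genes, BicD was positive and gnu negative, and the median of 0.02 lay at percentile 93.5 of random lists and at 97.8 of those matched on print row. Odorant-binding protein genes had no calls among 49, with a median of 0.045 at percentile 99.9, and at 98.0 with matching. Of the 7 genes of the vitelline membrane list, only the nuclear envelope gene fs(1)Ya was called, at 0.34, and the list median lay at percentile 54.4. The labels name Cy3 in the title and Cy5 in the channel field for the control IP of this array, and the sides given here take the Orb IP in Cy3 and the control IP in Cy5.

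Across the 3 IP arrays, with the dyes of the control IP array read by its channel field, 45 features were 2-fold or more on the positive side throughout. Of these, 39 have gene names. Independent lists would share 27.6, and Fisher's exact test across 13119 features gave a one-sided p of 0.000397, although genes are not independent replicates. The named genes included galla-1 at 1.05 against poly(A) RNA and 0.43 against the control IP, the TOR complex gene Lst8 at 0.89 and 0.31, the translation regulator Paip1 at 0.79 and 0.32, and the kinase gene Tlk at 0.75 and 0.35; these 4 were picked after their values were seen. On the negative side throughout were 3 features, where 26.7 would be shared, and the 1 with a name was His3:CG31613. Positive against poly(A) RNA but negative against the control IP were 26, where 21.9 would be shared (one-sided Fisher's exact p = 0.196). The opposite combination held 14, where 33.6 would be shared. Features called on the control IP array, on either side, were thus few among the poly(A) negative ones. If the dyes of that array were the reverse of its channel field, the 26 would be the shared positive features. After row centring 20 features were positive on all 3 arrays, where 14.2 would be shared. Over all features the mean ratio against poly(A) RNA and the ratio against the control IP correlated at r = -0.05 (Spearman's rho = -0.10, across 13756 features).

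The overlap of the genotype calls with the IP calls against poly(A) RNA was examined because the study concerns RNAs regulated by Orb. These IP calls hold no control IP, so they do not define messages associated with Orb. Among 13111 features measured in both, 616 were on the positive side of both, against 273.9 for independent lists, with a two-sided Fisher's exact p of 6.0e-108 across features. Only 10 were genotype positive and IP negative, against 333.1 (Fisher's exact p = 9.6e-155). Genotype negative features held 172 that were IP positive, against 236.9 (Fisher's exact p = 4.9e-07), and 243 that were IP negative, against 288.2 (p = 0.0014). Fisher's exact test takes the features as independent, which they are not, so these p-values measure no spread between arrays or samples. Shared positive genes included bcd, with genotype and IP log10 ratios of 0.71 and 0.71, rhi with 0.64 and 0.85, vas with 1.06 and 0.39, me31B with 1.29 and 0.41, the cap-binding factor eIF4E1 with 0.54 and 0.46, and the replication licensing gene Cdc6 with 0.67 and 0.49. Against the control IP all of these were within 2-fold: bcd at -0.15, rhi at 0.05, vas at -0.02, me31B at -0.14, eIF4E1 at -0.07 and Cdc6 at 0.07. Neither orb nor osk was IP positive against poly(A) RNA, at -0.18 and -0.07.

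Across 13759 features the genotype ratio and the IP ratio against poly(A) RNA correlated at r = 0.35 (Spearman's rho = 0.43), and at r = 0.33 with both centred on print rows. With row centring, 317 features were positive in both, against 126.6 for independent lists. The correlation came mainly from the 2 swapped genotype arrays. In deposited sign across positions, these correlated at 0.51 and 0.40 with the array with the IP in Cy3. With the IP in Cy5 they correlated at -0.54 and -0.39, and once turned both relations were positive. The 5 arrays with CS in Cy3 correlated at 0.01 to 0.05 with the IP in Cy3, which turns negative, and at 0.14 to 0.19 with the IP in Cy5. The genotype ratio and the ratio of Orb IP to control IP correlated at r = -0.0064.

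**Figure D4:**
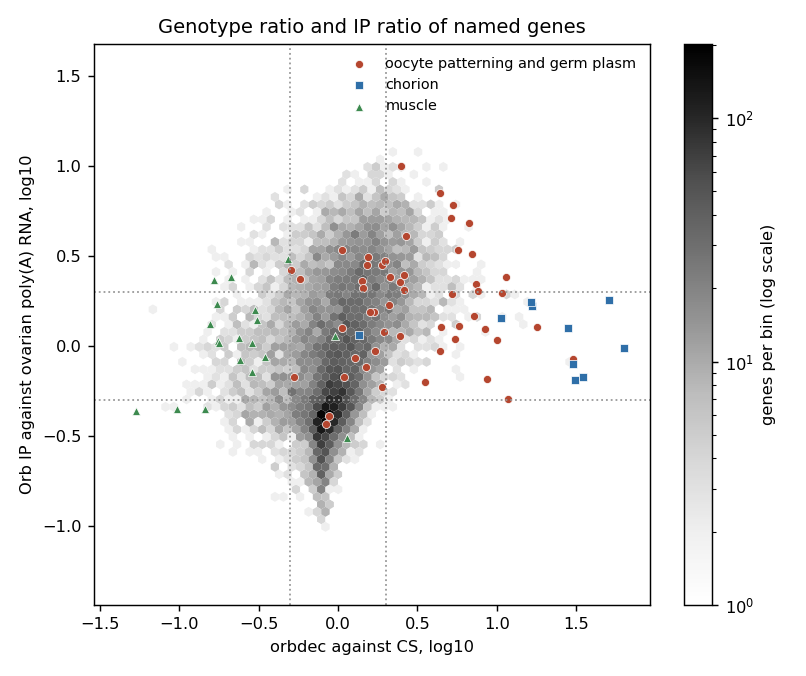
Genotype log10 ratio against mean Orb IP to poly(A) log10 ratio for named genes, shaded by genes per bin on a log scale, with red circles for oocyte patterning genes, blue squares for chorion genes and green triangles for muscle genes; dotted lines mark 2-fold. The 10 chorion genes had a median genotype ratio of 1.46 and a median IP ratio of 0.08.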

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

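Each value below was set apart because 1 of the 5 arrays with CS in Cy3 lay far from the other 4: the gap to its nearest neighbour, divided by the range of the 5, exceeded 0.71. Of 127 sets of 5 arrays looked at, 10 did so, where chance alone gives about 1 in 20, or 6.35. These arrays repeat the same RNA, and no biological explanation was tested.

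Replicate 3 had 501 missing positions, against 73 to 151 on the other arrays (gap over range 0.818). Its median of the RNP and translational repression list was 0.39, against 0.33 to 0.35 (0.751), and its ratio of the cuticle protein gene Acp1 was -1.59, against -1.48 to -1.43 (0.713). Replicate 1 had the lowest median of the vitelline membrane list, 0.89 against 0.92 to 0.93 (0.733), and the lowest value of the vitelline membrane gene psd, 0.89 against 0.92 to 0.93 (0.717). The list median there equalled the value of its member psd, 0.888, so these flags are not separate. On the same array the germline-enriched ribosomal protein gene RpS5b was at 1.03, against 1.18 to 1.20 (0.874), and the testis gene topi at -0.11, against 0.15 to 0.22 (0.788). Replicate 5 had the highest value of the nuclear receptor gene usp, 0.49 against 0.46 (0.912), and the lowest of the stress gene TotC, -0.93 against about -0.85 (0.895). The heat shock gene Hsp68 was at -0.17 on replicate 4, against -0.37 to -0.32 (0.756).

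A signal also appeared in spots that no comparison uses. Control positions formed a pair offset by a mean size of 1.07 and a pair offset by 0.485, in log10. These offsets are from the median of 5 other control kinds on the same array. They were seen on the 2 arrays with CS in Cy5 and the 3 IP arrays. On the 5 arrays with CS in Cy3 the same positions were offset by only 0.09 ± 0.04 (SD).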

How the results depend on the processing

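The rules fixed in advance assumed log2 ratios, and the log10 reading of the main results was adopted after the data were seen. Print-row centring and the log2 reading as an alternative were also added then. The other settings were planned, and causes were not tested unless a setting's own construction shows them. Counts are given as positive and negative side. No called gene among those named, and no list median outside the middle 95% of random lists, changed sign. For called genes the rule largely fixes this, since a call needs the same sign on every array. Leaving out or reweighting arrays cannot turn such a gene, and only settings that re-centre the arrays could. Of the list medians inside that range, 23 alternative values of 15 medians changed sign or reached 0, among them IP medians after print-row centring (muscle 0.03 to -0.17, chorion 0.08 to -0.05, oxidative phosphorylation 0.09 to -0.01) and the testis genotype median, -0.04, which was 0.09 on the arrays with CS in Cy3 and -0.18 on the swapped arrays. Of 102 alternative counts 63 stayed within 1.5 times the main one and 39 did not. Of 456 list medians 377 and of 1858 values of named genes 1679 moved by at most 1 SD over arrays or, with 1 array, kept their sign. For a named gene measured on all arrays of a comparison, leaving out 1 array cannot move the mean by more than 1 SD, by arithmetic. The share of named genes therefore says little about stability to single arrays. For the genotype ratio (1586 and 1470), a 1.5-fold threshold gave 2591 and 2253 and a 3-fold one 639 and 768. Limma over the arrays, which compares the RNA samples and drops the threshold of size, gave 4667 and 5299, with the slide series as a term 4729 and 5389, and with the replicate block 4686 and 5313. Replicate numbers only count arrays: deviations of same-numbered arrays correlated at -0.07 and 0.07 and the fitted correlation within a number was -0.04, so the numbers do not pair arrays, and with the 2-fold threshold the block gave 1665 and 1525. The 2 swapped arrays alone gave 2243 negative features. Leaving out single arrays gave 1486 to 1703 and 1472 to 1540. For the IP against poly(A) RNA, limma with a 3-fold threshold gave 1808 and 1177 and with print-row centring 930 and 676. The 2-fold counts there (2264 and 2754) became 3413 and 4349 at 1.5-fold, 1052 and 786 at 3-fold, and 1199 and 986 with print-row centring. With 1 array left out they ranged from 2926 to 3655 and from 3435 to 4261, a value with no test in which fewer arrays must pass; without the array with the IP in Cy3 they were the higher values. The control IP array gave 874 and 755 at 1.5-fold and 37 and 24 at 3-fold. Features positive on all 3 IP arrays (45) numbered 265 at 1.5-fold, 10 at 3-fold and 20 with print-row centring. The IP positive features with a genotype call (788) numbered 1796, 138 and 387 in the same order. Read as log2, the values gave 62 and 31 for the genotype, 8 and 2 for the poly(A) arrays at 2-fold, and 1 and 0 for the control IP array, since 2-fold is then a larger step. With random lists matched on print row, also added after the data were seen, 19 of 24 list medians lay outside their middle 95% for the genotype, the same 19 as with free lists. For the IP against poly(A) RNA 10 did, against 8 with free lists, and only 4 were shared (oocyte patterning, RNP, odorant-binding and testis), while cell cycle, ribosomal protein, translation factor and heat shock lists no longer did. The 6 gained were the proteasome list on the positive side and the immune, P450, digestive, phototransduction and accessory gland lists on the negative side. For the control IP array 4 did, against 3. Limma with 1 poly(A) array was not fitted. Signal over background was not used here.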

Other observations

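The 12 gene families in this part, and every test below except those on dye bias in the shared calls, on ovary genes and on the neighbours of orb, were chosen only after the results they bear on were seen. Sides are those of the report. Nuclear pore and splicing genes joined the positive side of the genotype ratio. Of 20 nucleoporin genes, 13 were positive and 0 negative, with a median log10 ratio of 0.38 above all 10000 random list medians, led by Nup98-96 at 0.65 ± 0.11 (SD, n = 7 arrays) and Nup35 at 0.61 ± 0.14. Of 10 spliceosomal snRNP protein genes 7 were positive and 0 negative, with SmD3 at 0.65 ± 0.06 and SmD1 at 0.61 ± 0.12. Mediator subunits of the transcription machinery gave 6 positive and 0 negative among 24, led by MED20 at 0.46 ± 0.24, and tRNA synthetases 4 and 0 among 15, led by CysRS at 0.43 ± 0.28. Of 9 kinesin-like genes 3 were positive and 0 negative, with the mitotic motor Klp61F at 0.69 ± 0.22. After print-row centring of the IP ratio, 4 of the 10 snRNP genes and 4 of the 9 kinesin-like genes were positive and 0 negative, with SmE at 0.70 ± 0.06 (SD, n = 2 arrays) and Klp61F at 0.62 ± 0.14. Nucleoporins gave 2 and 0, Mediator subunits 2 and 0 and tRNA synthetases 1 and 0.

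Of the remaining families, UDP-glycosyltransferases and tetraspanins stood apart on the negative side of the genotype ratio. Of 35 UDP-glycosyltransferase genes 15 were negative and 0 positive, with a median of -0.19 below all 10000 random list medians and with Ugt37A3 at -0.81 ± 0.19. Tetraspanins gave 12 negative and 4 positive among 34, with a median at percentile 0.13, led by Tsp42Eb at -0.88 ± 0.12. The medians of the others lay within the middle 95% of random lists: cuticle protein genes gave 11 and 1 among 88 (percentile 4.06), serpins 7 and 0 among 27 (8.70), chitinases 2 and 1 among 10 (13.7) and vacuolar ATPase subunits 4 and 0 among 30 (21.1). Chemoreceptor genes gave 0 negative and 1 positive, Ir76a at 0.45 ± 0.22, among 163 (2.68). In the row-centred IP ratio cuticle protein genes gave 22 negative and 2 positive calls among 79, with a median of -0.29 below all 10000 random list medians. Chemoreceptors gave 7 and 3 among 140, with a median of -0.11 also below all of them, serpins 4 and 1 among 22 (percentile 0.06) and chitinases 3 and 0 among 9 (0.27). Within the middle 95% were UDP-glycosyltransferases with 3 and 2 among 30, vacuolar ATPase subunits with 5 and 5 among 29 and tetraspanins with 0 and 0 among 32.

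Chorion, vitelline membrane, oocyte patterning and RNP lists lay on the positive side of the genotype ratio and 7 body lists on the negative side, while follicle cell regulators (percentile 73.2) and yolk genes (median -0.31) did not follow. Gene-specific dye bias would oppose the orientations, but their turned means correlated at r = 0.604 across features, which argues against it as the whole source. A different share of ovary RNA in the females alone would move all body lists alike if every member lay well above background. The medians of the 7 lists spanned 0.525, more than in all but 38 of 10000 shufflings of their 194 members (permutation p = 0.0039), but intensities were not used, and genes near background could spread the medians in the same way. A share difference therefore stays open, together with differences in body size, age or strain and with orb itself.

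The ratio of Orb IP to poly(A) RNA depended on print row: 89.7% of negative calls lay in the first 5 rows, which held 33.6% of features, and 66.0% of positive calls in the last 6 rows, which held 30.2%. Chemoreceptor genes, which the ovary is not known to use, were taken as a probe of this. Their median was 0.52 higher in the last 6 rows than in the first 5, so different kinds of genes in different rows did not account for the dependence in this family. Row medians of these genes and of all other features correlated at r = 0.737 over the 15 rows that hold them, between the bounds set for and against a position effect on the slide, and some rows held only 1 such gene. Position on the slide is a possible explanation that these values leave open, and no biological explanation was tested.

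Genotype and IP calls against poly(A) RNA shared the positive side, and print row could not account for this, since r was 0.331 after both were centred on rows. Dye effects of equal size in both orientations cancel in both means by construction. Given dye-bias estimates for both, the partial r fell from 0.360 to 0.202, with a lower 95% bound of 0.186. The partial r passed the bound of 0.2 set before the test, but by less than its spread, a demand added after the value was seen. These estimates measure the part that cancels, so the value decides nothing about dye effects that differ between orientations. Such effects were not tested, but the relation itself depended on the orientation of the genotype arrays. In deposited sign the 2 swapped arrays correlated at 0.51 and 0.40 with the array with the IP in Cy3, the 5 others at only 0.01 to 0.05. An effect particular to the swapped arrays therefore stays open. Across 122 genes of the 5 ovary lists alone r was -0.0026, with an upper 95% bound of 0.175. A low r was predicted if the relation contrasts ovary genes with genes the ovary does not use. But genotype negative features, on the side of the body lists, were IP negative less often than independent lists give (243 against 288.2). The chorion and vitelline membrane lists, with genotype medians of 1.46 and 1.16, had IP medians of 0.08 and 0.14, which could itself lower r. The low r therefore does not decide for this contrast.

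Differences between the strains around the orb locus would raise the number of called genes near it. Among the 20 nearest measured genes of orb 2 were called, against a median of 4 over 11513 windows of 20 neighbouring genes, and this count lay at percentile 6.93, which gives no sign of such a block.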
